A study of Rattus norvegicus and Saccharomyces cerevisiae and Caenorhabditis elegans with 17 samples.

How the data were processed

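Transcript levels were measured on Affymetrix arrays, 1 array type per organism, in rat liver (3 arrays per diet), in the nematode Caenorhabditis elegans (2 biotin-sufficient and 3 biotin-deficient arrays) and in the yeast Saccharomyces cerevisiae (3 arrays per biotin concentration). Per the labels' protocols, RNA was extracted with TRIzol and cleaned on columns, and 5 µg of total RNA was labelled with a one-cycle cDNA synthesis and in vitro transcription. A few added bacterial transcripts serve as controls on such arrays: poly-A controls go in before labelling and hybridization controls after it. The amount of poly-A control added per worm sample is not known. The deposited values are linear signal intensities, 1 per probe set, and GCOS 1.4 is the only tool in the submitters' processing notes. The signal algorithm and the chip definition are not given in the sources used here. The mean of each deposited array, after leaving out its extreme values, lay between 500.11 and 500.3 signal units, so the deposited intensities had been scaled to a common level per array. The shape of the distributions had not been made equal: on the log2 scale, the array medians of the deposited intensities spanned 0.223 in rat, 0.973 in worm and 0.157 in yeast.

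From these deposited intensities, log2(signal + 16) was computed, so fold changes of dim probe sets are understated. At least 1 quartile differed between arrays by more than 0.1 in every organism, so quantile normalization was applied within each organism. In yeast only the median did, by 0.111. Array control probe sets and, on the yeast array, the probe sets with a symbol named for the fission yeast Schizosaccharomyces pombe were left out, and probe sets with no symbol, which can be of either yeast, were kept. Rat and worm probe sets under the 40th percentile of mean log2 intensity were left out, which corresponds to a signal of 58.2 in rat and 68 in worm. Yeast probe sets under the 95th percentile of the 630 probe sets named for S. pombe, a signal of 10.5, were left out. This left 18625 rat, 13529 worm and 5803 yeast probe sets. Arrays give no counting depth, and their number limits the precision. Each organism was fitted alone with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment over the probe sets tested), with an adjusted p under 0.05 as the threshold. Changes are deficient minus sufficient. Signals are given as deposited, while log2 changes and their standard errors come from the normalized values, so the ratio of the printed signals can differ from the log2 change.

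Gene symbols came from the platform's annotation. In rat, 20832 probe sets had 1 symbol, 436 several and 9831 none. In worm, these numbers were 20766, 887 and 972. On the yeast array only 938 probe sets had an S. cerevisiae symbol here, so the yeast gene lists were measured in small part, and 9360 probe sets had none. A gene was represented by the probe set with the highest mean, among probe sets with 1 symbol. Gene lists of pathways, responses and cell types were fixed before the data were examined, as were the tests, the named genes and all alternatives except those named below as added. Lists with at least 4 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The 24 rat, 26 worm and 9 yeast lists were adjusted separately. No list was called in any organism with an estimated correlation.

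The genes named were the 6 with the largest rise and the 6 with the largest fall among those past the threshold whose groups did not overlap, the 3 members with the smallest p of each called list, the 2 with the smallest p of each list shared by the organisms, and every measured gene of the biotin lists. Differences between organisms in the mean shift of a shared list were tested by exact two-sided permutation of the biotin labels within each organism. The p-values were adjusted over 16 comparisons. Labels were permuted in both organisms of a pair, so the null is no biotin effect in either. A shift in a single organism can thus give a small p, which does not by itself show that the organisms differ. The smallest p these permutations can give is 0.005.

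The steps after normalization were tested on simulated data with no true difference plus known changes. Values were drawn independently for each probe set, and few probe sets were changed. The simulation therefore did not test the normalization, the effect of correlation between genes on the list calls, or a change as wide as in worm. In the rat simulation of 18625 probe sets, 32.8% of probe sets changed by 1.5-fold, 49.3% of those changed by 2-fold and 84.8% of those changed by 4-fold were recovered. For worm, with 13529 probe sets, these shares were 16.4%, 58.2% and 87.9%, and for yeast, with 5803, they were 83.6%, 97% and 100%. False calls made up 3.48% of calls in rat, 1.82% in worm and 3.11% in yeast. With no change simulated, 0 lists were called in any organism, and a list moved by 0.5 was recovered at 0.506 in rat, 0.498 in worm and 0.494 in yeast.

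Alternatives covered the normalization, the offset, the filter, the variance model, array weights, a fold threshold, each array left out in turn, a replicate block, the gene set test and the choice of probe set. Centring on the poly-A or the hybridization controls, median centring for the differences between organisms, the worm ribosomal protein list without rpa-1 and rpa-2, and the marker lists of the closing section, were chosen after seeing the data. The labels describe individually housed rats and triplicate yeast cultures. They do not say whether the worm arrays came from separate cultures, so the worm p-values measure only the spread between these samples, which may be technical. Of the 5 rats stated per diet, 3 arrays per diet were analysed here. Figures were drawn with matplotlib 3.10.9.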

Results

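The series set biotin-deficient against biotin-sufficient samples of rat liver, C. elegans and S. cerevisiae to find which transcripts change with biotin supply. Biotin is the vitamin bound to carboxylases such as pyruvate carboxylase and acetyl-CoA carboxylase. Male Wistar rats, 21 days old at the start, ate a diet with 30% egg white, whose avidin binds biotin, or a similar diet without avidin, and livers were taken at 6 to 7 weeks. N2 worms grew from the L1 to the L4 larval stage on an E. coli strain that cannot make biotin, in medium with 5 nM or 0.05 nM biotin and with 2 U/ml avidin in both. Yeast of strain W303-1A grew in 2% dextrose with 8 nM or 0.4 nM biotin and was harvested at an A600 of 0.6 to 0.8. Pearson correlations of log2 signals across probe sets, which are not independent replicates, were 0.975 to 0.981 between rat arrays of 1 group and 0.954 to 0.964 between groups. In worm they were 0.977 to 0.990 within groups and 0.742 to 0.814 between them, and in yeast 0.995 to 0.997 and 0.976 to 0.981.

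In the livers of biotin-deficient rats, Lcn2 and Cyp1a1 rose the most among the genes called. Lcn2, which encodes the siderophore-binding protein lipocalin 2, went from a signal of 99.3 ± 3.72 to 18670 ± 11400 (SD, n = 3 per diet), a log2 change of 7.13 (SE 0.304). Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, went from 97.4 ± 13.6 to 7468 ± 485 (log2 change 6.02, SE 0.108). Of 19 genes of fatty acid synthesis 11 fell, with Elovl5 at a log2 change of -1.47 (SE 0.101), and of 9 genes of gluconeogenesis 6 rose, with Gpt, alanine aminotransferase, at 1.07 (SE 0.0811). Neither list was past the threshold with an estimated correlation between genes (adjusted p = 0.213 each). Among the biotin-dependent carboxylases, pyruvate carboxylase, Pc, fell by 0.43 (SE 0.0894), and no other was past the threshold.

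The other leading rises were Akr1b7, an aldose reductase-like enzyme (log2 change 5.22, SE 0.404), the protease inhibitor A2m (4.64, SE 0.443), the sulfotransferase Sult2a2 (4.17, SE 0.441) and Acsm3, a medium-chain acyl-CoA synthetase (3.72, SE 0.16). The leading falls were Stac3 (63.8-fold lower, SE 0.161 on the log2 scale), Dhrs7l1 (-5.84, SE 0.398), the peroxisomal hydroxyacid oxidase Hao2 (-4.48, SE 0.12), the cadherin Cdh17 (-4.48, SE 0.493), the odorant-binding protein gene Obp3 (-4.02, SE 0.476) and Nrep (-3.87, SE 0.172). Stac3 went from a mean signal of 5717 to 74.8 and Hao2 from 15590 ± 927 to 709 ± 128 (SD, n = 3). The sufficient signal of Akr1b7 averaged 29.3, under the filter's floor of 58.2, and its change was 4.14 with an offset of 64 in place of 16. The limma adjusted p-values of these 12 genes ranged from 2.69e-10 for Cyp1a1 to 0.000251 for Obp3.

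Of 11 measured genes for biotin enzymes, their ligase and biotin transport, 2 fell and 9 were not past the threshold, over all probe sets tested and adjusted over the list alone. Slc16a1, a monocarboxylate transporter, fell by 0.70 (SE 0.0799, limma adjusted p = 0.000206), and Pc had an adjusted p of 0.00782. The values of the others were -0.31 for Btd (biotinidase), -0.26 for Pcca, -0.19 for Hlcs (the ligase that attaches biotin), -0.14 for Mccc2, -0.05 for Acacb, 0.04 for Pccb and for Acaca, 0.06 for Slc5a6 and 0.15 for Mccc1. As a list they were not called (camera adjusted p = 0.194).

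In fatty acid synthesis, 11 of 19 measured genes fell and none rose, and 13 fell when adjusted over the list alone. The list mean was -0.81 (camera adjusted p = 3.24e-07, and adjusted p = 0.213 with an estimated correlation). Elovl5, a fatty acid elongase, went from 19940 ± 763 to 7295 ± 1010, Srebf1, the lipogenic transcription factor, fell by 0.88 (SE 0.0759), and Me1, malic enzyme, fell by 1.26 (SE 0.112). Of 9 measured gluconeogenesis genes, 6 rose and none fell, with 7 rising when adjusted over the list alone, and the mean was 0.71 (adjusted p = 0.000362, and adjusted p = 0.213 with an estimated correlation). Beside Gpt, the coactivator gene Ppargc1a rose by 1.68 (SE 0.129) and the aspartate aminotransferase gene Got1 by 0.84 (SE 0.172). In glycolysis, 3 of 13 genes rose and 3 fell, and 4 rose and 3 fell when adjusted over the list alone. Pklr, the liver pyruvate kinase, fell by 1.24 (SE 0.121), and Pgam1, phosphoglycerate mutase, rose by 0.60 (SE 0.0624). The glycolysis list was not called (adjusted p = 0.513), and its mean of -0.005 and median of 0.13 differed in sign.

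Transcripts of cytosolic ribosomal proteins rose in small steps: 27 of 41 rose and none fell, and 33 rose and 1 fell when adjusted over the list alone. The mean was 0.26 (adjusted p = 1.84e-14, and adjusted p = 0.209 with an estimated correlation), with 0.61 for Rpl12, 0.57 for Rpl7a and 0.56 for Rpl21. In the TCA cycle, 4 of 16 genes rose and none fell, and 5 rose and 1 fell when adjusted over the list alone. Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase, rose by 1.12 (SE 0.0858) and Suclg2 by 0.35 (SE 0.0744), and the list was not called (adjusted p = 0.09). In fatty acid oxidation, 6 of 20 rose and 4 fell, or 8 and 6 when adjusted over the list alone (adjusted p = 0.513), with Pdk4, a kinase that inhibits pyruvate dehydrogenase, up by 1.35 (SE 0.0965) and Hadh, a mitochondrial hydroxyacyl-CoA dehydrogenase, down at -0.69 (SE 0.0755). In oxidative phosphorylation, 2 of 26 rose, Cox4i1 at 0.22 (SE 0.0583) and Atp5po at 0.21 (SE 0.06), and 0 did when adjusted over the list alone (adjusted p = 0.34). The sign of that list's mean turned under median centring, to -0.07.

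Bile acid genes also changed: 4 of 9 rose and 1 fell, with the same counts when adjusted over the list alone. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 0.80 (SE 0.0654), Cyp27a1 by 0.66 (SE 0.0565) and the bile acid-CoA ligase Slc27a5 by 0.71 (SE 0.0825). The list mean was 0.23 (adjusted p = 0.0253, and adjusted p = 0.213 with an estimated correlation), and its adjusted p was 0.0548 under median centring, 0.117 with poly-A control centring and 0.0568 without sufficient replicate 1. Growth hormone responsive genes fell, 7 of 10 with none rising, over all probe sets tested and adjusted over the list alone. Their mean was -0.55 (adjusted p = 1.64e-06, and adjusted p = 0.0697 with an estimated correlation). Cyp2c11, the male-predominant cytochrome P450, went from 43130 ± 923 to 20410 ± 3350, Igfals fell by 1.17 (SE 0.1) and Igf1 fell by 0.52 (SE 0.0582).

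Acute phase genes rose, 8 of 11 with none falling, and 9 rose and 1 fell when adjusted over the list alone. The mean of 1.27 rested on Lcn2 and A2m, and the median was 0.22 (adjusted p = 9.07e-07, and adjusted p = 0.0697 with an estimated correlation). Orm1, an acute phase glycoprotein, went from 31140 ± 1410 to 60210 ± 3720. Markers of macrophages rose in the same livers, 7 of 8 (7 when adjusted over the list alone), with a mean of 0.58 (adjusted p = 5.68e-06, and adjusted p = 0.0895 with an estimated correlation). Cd163 rose by 0.84, C1qb by 0.78 and C1qc by 0.69. Endothelial markers rose in 3 of 6 cases (4 when adjusted over the list alone), with Kdr at 0.71, Lyve1 at 0.54 and Stab2 at 0.46 (list mean 0.39, adjusted p = 0.0195, and adjusted p = 0.364 with an estimated correlation). Hepatocyte markers had a mean of -0.14, and 2 of 7 fell (4 when adjusted over the list alone). Ahsg was at -0.40, Apob at -0.23 and Apoc3 at -0.15, with an adjusted p of 0.05 for Apoc3. Of the 5 scalings tried, the hepatocyte list was called only under quantile normalization (adjusted p = 0.0253, and adjusted p = 0.236 with an estimated correlation), with 0.528 as deposited, and another Apob probe set was at 0.56. Stellate cell and fibroblast markers (1 of 7 rose, 3 fell) and lymphocyte markers (0 of 4 past the threshold) were not called, and the stellate list had a mean of 0.01 and a median of -0.33.

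**Figure D1:**
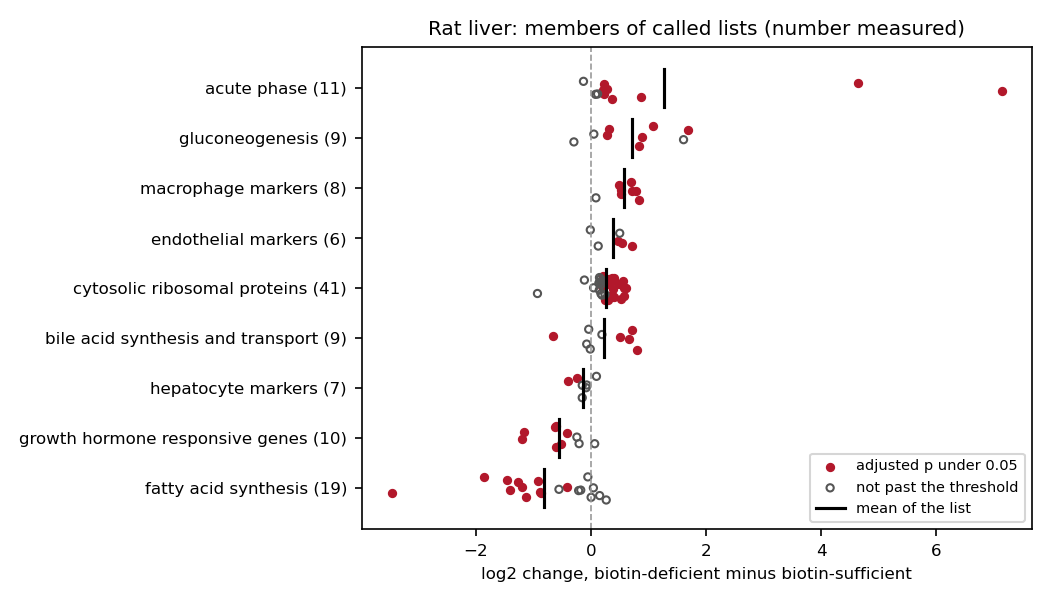
Members of the 9 called gene lists in rat liver. The x axis is the log2 change, deficient minus sufficient (n = 3 arrays per diet), each point is a gene, filled where its adjusted p was under 0.05, and black bars are list means. Fatty acid synthesis lies furthest left with a mean of -0.81, and the acute phase mean of 1.27 is set by Lcn2 and A2m.

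In all, limma called 2895 of 18625 rat probe sets, 1470 higher and 1425 lower in the deficient livers. Of these, 244 rose and 225 fell by at least 2-fold. Over all 18625, 5361 had an unadjusted p under 0.05. The values of the diets did not overlap for 33.6% of probe sets, where chance gives 10%. With median centring the split was 965 higher and 1986 lower, and without sufficient replicate 3 the count was 1884.

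Worms on low biotin differed from worms on sufficient biotin at most transcripts measured. cpr-2, a cathepsin B-like protease gene, went from a signal of 34.4 ± 3.37 (SD, n = 2) to 14190 ± 1140 (SD, n = 3), a log2 change of 7.72 (SE 0.105). hsp-12.6, a small heat shock protein gene regulated by DAF-16, rose by 6.36 (SE 0.25), while fat-7, a stearoyl-CoA desaturase gene, fell by 4.15 (SE 0.124). All 14 measured innate immunity genes rose, and all 16 measured oocyte and eggshell genes fell. Each of these lists kept its direction under the 5 scalings tried.

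The median change of all worm probe sets was -0.14 under quantile normalization, 0.15 as deposited, -0.65 under median centring, -0.72 with poly-A control centring and -0.03 with hybridization control centring. Shifts of called worm lists are given relative to all other genes, whereas list means, in the figures and the comparison of organisms, move with the scaling. Other leading rises were grl-23, of the ground-like family (7.09, SE 0.554), the collagen genes col-158 (6.09, SE 0.421) and col-37 (5.87, SE 0.615), and F53A9.8 (5.81, SE 0.0954). The sufficient signals of grl-23, col-158 and col-37 averaged 2.67, 14.1 and 3.94 and those of cpr-2 and hsp-12.6 averaged 34.4 and 22.3, all under the filter's floor of 68. The sizes and order of these rises therefore depend on the offset: with 64 in place of 16, grl-23 was at 5.33, hsp-12.6 at 5.32, col-158 at 4.81 and col-37 at 4.25, beside 5.61 for F53A9.8. Other leading falls were T05E12.6 (-4.99, SE 0.169), srh-237, of a chemoreceptor family (-4.24, SE 0.212), Y17D7B.7 (-3.82, SE 0.23), icmt-1 (-3.80, SE 0.203) and the nuclear receptor gene nhr-114 (-3.73, SE 0.215). The deficient signal of srh-237 averaged 32.6, also under the floor, and its change was -3.23 with the offset of 64. The limma adjusted p-values of the 12 leading genes were between 6.25e-09 for cpr-2 and 5.37e-05 for col-37.

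Of 6 measured genes of biotin enzymes and their ligase, 3 rose and 3 fell, over all probe sets tested and adjusted over the list alone, and the list was not called (adjusted p = 0.762, with a positive camera direction beside a mean of -0.02). Both propionyl-CoA carboxylase subunits rose, pcca-1 by 0.89 (SE 0.0996) and pccb-1 by 0.67 (SE 0.0797), and pyc-1, pyruvate carboxylase, rose by 0.36 (SE 0.118). mccc-1, a methylcrotonyl-CoA carboxylase subunit, fell by 0.70 (SE 0.137), pod-2, acetyl-CoA carboxylase, fell by 0.90 (SE 0.252) and bpl-1, the biotin ligase, fell by 0.41 (SE 0.146). The direction of pcca-1, pccb-1, pyc-1 and bpl-1 turned under at least 1 other scaling, and another pccb-1 probe set was at -0.28.

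Innate immunity genes rose by 2.46 relative to other genes, 14 of 14 over all probe sets and adjusted over the list alone (camera adjusted p = 5.27e-07, and adjusted p = 0.465 with an estimated correlation). The C-type lectin gene clec-60 rose by 4.87 (SE 0.156), the lysozyme gene lys-7 by 3.90 (SE 0.134) and the antimicrobial peptide gene nlp-29 by 3.68 (SE 0.123). Genes regulated by DAF-16, the FOXO factor of insulin-like signalling, or by starvation rose in 9 of 14 cases and fell in 4, with the same counts when adjusted over the list alone. dod-3 went from 148 ± 7.34 to 6857 ± 86.9 and the metallothionein gene mtl-1 from 190 ± 17.8 to 7962 ± 214 (SD, n = 2 and 3). The list stood 1.81 above other genes (adjusted p = 0.0117, and adjusted p = 0.465 with an estimated correlation). Heat shock and unfolded protein response genes fell in 7 of 9 cases and rose in 1, also when adjusted over the list alone. hsp-4, the worm BiP, fell by 1.56 (SE 0.0953), hsp-16.41 fell by 2.76 (SE 0.174) and hsp-1 fell by 0.83 (SE 0.0548). Their shift was -1.08 (adjusted p = 0.0227, and adjusted p = 0.465 with an estimated correlation).

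In the methionine and S-adenosylmethionine cycle, 8 of 10 genes fell and 2 rose, also when adjusted over the list alone, with a shift of -0.98 (adjusted p = 0.0227, and adjusted p = 0.465 with an estimated correlation). Its adjusted p was 0.0834 under median centring. mel-32, serine hydroxymethyltransferase, fell by 1.82 (SE 0.0818). The phosphoethanolamine methyltransferases, which use S-adenosylmethionine to make phosphocholine, went apart: pmt-1 rose by 1.44 (SE 0.0622) and pmt-2 fell by 1.68 (SE 0.0907). Among 4 gluconeogenesis and glyoxylate genes, 3 rose and 1 fell, with pck-1, phosphoenolpyruvate carboxykinase, at 1.88 (SE 0.104) and icl-1, of the glyoxylate cycle, at 1.90 (SE 0.151), and the list was not called (adjusted p = 0.211). In fatty acid synthesis, 10 of 19 fell and 5 rose (adjusted p = 0.332, called with poly-A control centring at 0.0347), with acs-1, an acyl-CoA synthetase, at -1.82 (SE 0.0916) beside fat-7. In fatty acid oxidation, 11 of 24 rose and 10 fell, with maoc-1 at 1.79 (SE 0.103) and ech-6 at -1.27 (SE 0.0778). In the TCA cycle, 11 of 24 rose and 8 fell, and sdha-2 was at -1.94 (SE 0.156) and sucg-1 at -1.21 (SE 0.0987). Counts in these 4 lists were the same when adjusted over the list alone. Neither of the last pair was called (adjusted p = 0.805 each). Their camera direction was positive, beside a median of -0.04 for fatty acid oxidation and -0.02 for the TCA cycle.

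Glycolysis genes rose in 7 of 14 cases and fell in 4, with gpd-3 at 0.61 (SE 0.056, but -0.04 with poly-A control centring) and pgk-1 at -0.80 (SE 0.0979). In oxidative phosphorylation 12 of 29 rose and 4 fell, with ucr-2.1 at 1.54 (SE 0.121) and asb-2 at a 2.64-fold rise. These counts were the same when adjusted over the list alone. On the list of 63 cytosolic ribosomal protein genes, 1 rose and 6 fell, or 0 and 4 when adjusted over the list alone. The lowest p-values were those of rpa-1 at -0.88 (SE 0.106) and rpa-2 at -0.81 (SE 0.0952), symbols that now stand for replication protein A genes and entered the list as older names of ribosomal proteins. Without this pair, a choice made after seeing the data, 1 of 61 rose and 4 fell, or 0 and 1 when adjusted over the list alone, and the mean was -0.02 (adjusted p = 0.966). The 4 were rpl-11.1 at -0.46, rpl-41.1 at -0.43, rps-13 at -0.20 and rps-24 at -0.17, and rpl-11.2 rose by 0.19. None of these 3 lists was called, with adjusted p-values of 0.424 for glycolysis, 0.104 for oxidative phosphorylation and 0.805 for the ribosomal proteins, and the sign of each list's mean turned under at least 1 other scaling. The ribosomal protein list was below other genes under median centring (adjusted p = 3.77e-05, and 6.49e-05 without rpa-1 and rpa-2).

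Oocyte and eggshell transcripts fell, while markers of muscle, neurons and intestine rose. The oocyte and eggshell list stood -1.37 below other genes, 16 of 16 members falling over all probe sets and adjusted over the list alone (adjusted p = 1.67e-05, and adjusted p = 0.545 with an estimated correlation). glh-1, a germ granule helicase gene, fell by 1.71 (SE 0.0852), the yolk receptor gene rme-2 fell by 1.69 (SE 0.115) and oma-1 fell by 1.44 (SE 0.11). Body muscle markers rose in 8 of 8 cases, with unc-22 at 2.33, unc-54 at 1.68 and tnt-2 at 1.67. Neuron markers rose in 7 of 8 cases and fell in 1, with egl-3 at 2.23, sbt-1 at 2.02 and egl-21 at 1.89. Intestine markers rose in 6 of 8 cases, with ifb-2 at 2.25, asp-1 at 1.34 and cpr-1 at 1.33. These 3 lists had the same counts when adjusted over the list alone. Their shifts were 1.31, 1.28 and 0.95, with adjusted p = 0.000656, 0.00885 and 0.0157, and adjusted p = 0.478, 0.478 and 0.465 with an estimated correlation. The intestine call was lost as deposited (0.0536), under median centring (0.08) and with poly-A control centring (0.169), and the muscle call with poly-A control centring (0.075).

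Cuticle genes changed in number. Of 95 collagen genes, 65 rose and 10 fell, also when adjusted over the list alone, a shift of 1.19 (adjusted p = 1.54e-06, and adjusted p = 0.536 with an estimated correlation). col-129 rose by 2.24 (SE 0.115) and col-98 was 4.61-fold higher, whereas col-101 fell by 2.47 (SE 0.126). Molting genes rose in 8 of 11 cases and fell in 1, also when adjusted over the list alone, with mlt-11 at 2.13, mlt-8 at 2.00 and noah-1 at 1.71, and a shift of 0.92 (adjusted p = 0.0214, and adjusted p = 0.478 with an estimated correlation). Of 23 major sperm protein genes, a family of near-identical copies whose probe sets can share signal, 12 rose and 11 when adjusted over the list alone. msp-74 was at 0.82, msp-142 at 0.75 and msp-3 at 0.60. Their list mean of 0.39 turned to -0.41 under median centring and to -0.48 with poly-A control centring. The call (adjusted p = 0.00885, and adjusted p = 0.663 with an estimated correlation) held only under quantile normalization. The adjusted p was 0.0879 as deposited, 0.418 under median centring, 0.949 with poly-A control centring and 0.235 with hybridization control centring, and the shift of 0.34 relative to other genes was 0.04 under each of these.

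**Figure D2:**
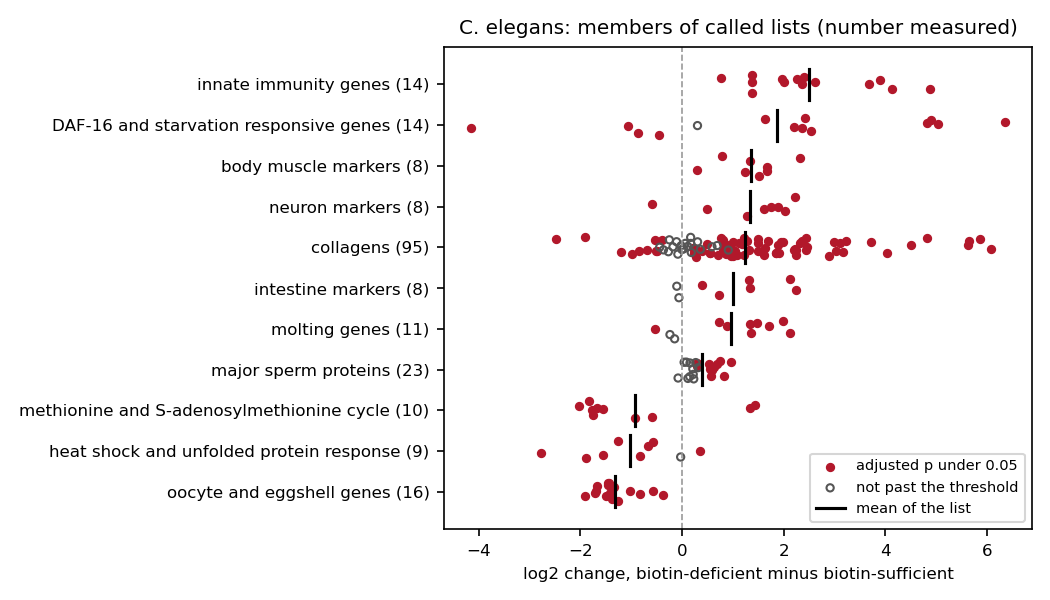
Members of the 11 called gene lists in C. elegans under quantile normalization. The x axis is the log2 change, deficient minus sufficient (n = 3 and 2 arrays), each point is a gene, filled where its adjusted p was under 0.05, and black bars are list means. All 16 oocyte and eggshell genes lie left of 0 and all 14 innate immunity genes right of it. The mean of the major sperm proteins, 0.39 here, turned to -0.41 under median centring and to -0.48 with poly-A control centring.

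In all, limma called 9975 of 13529 worm probe sets (73.7%), 4355 higher and 5620 lower on low biotin, and 2477 rose and 2323 fell by at least 2-fold. The groups did not overlap for 83.8% of probe sets, where chance gives 20%. The split was 5879 higher and 4725 lower as deposited, 3252 and 7704 under median centring and 2240 and 6887 with poly-A control centring. The added poly-A controls themselves had a higher deposited signal in every deficient array, by 0.86 on the log2 scale.

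In yeast at low biotin, SPG4 rose and the respiratory genes CYC1 and NDE1 fell. SPG4, a gene of stationary phase, went from a signal of 181 ± 31 to 1023 ± 67.9 (SD, n = 3), a log2 change of 2.34 (SE 0.0952). CYC1, the main cytochrome c, went from 1040 ± 66.6 to 196 ± 71.5 and NDE1, an external NADH dehydrogenase, from 1976 ± 227 to 331 ± 130. All 10 measured ribosome biogenesis genes fell. ACC1, acetyl-CoA carboxylase and the only biotin enzyme measured under a symbol here, fell by 0.29 (SE 0.0509, limma adjusted p = 0.00134).

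The further leading rises were CAT2, carnitine acetyltransferase (1.38, SE 0.0915), COX5B, the hypoxic isoform of a cytochrome c oxidase subunit (1.19, SE 0.0596), the amino acid permease gene GAP1 (1.09, SE 0.0661), MCT1 (1.00, SE 0.0603) and BAT2, the cytosolic branched-chain aminotransferase (0.98, SE 0.0476). The further leading falls were the cytochrome b5 gene CYB5 (-1.29, SE 0.116), the amino acid permease gene TAT1 (-1.14, SE 0.0802), the alcohol acetyltransferase gene ATF2 (1.99-fold lower, SE 0.141 on the log2 scale) and ALT2 (1.99-fold lower, SE 0.0961). Limma adjusted p-values of the 12 leading genes ranged from 9.84e-08 for SPG4 to 0.000395 for ATF2. These ranks hold only among genes with a symbol, 934 of the 5803 probe sets tested. Of all probe sets tested, 23 rose and 4 fell by at least 4-fold, and SPG4 was the only named rise of that size. Of the list of biotin uptake, synthesis and ligation, only TPO1, a polyamine transporter gene, was measured under a symbol, and it fell by 0.64 (SE 0.0663).

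The ribosome biogenesis list had a shift of -0.44 relative to other genes, with 10 of 10 members falling over all probe sets and adjusted over the list alone (adjusted p = 2.86e-05, and adjusted p = 0.402 with an estimated correlation). The RNA helicase gene DBP2 fell by 0.74 (SE 0.0614), and NOP2 and NOP58, of ribosomal RNA modification, fell by 0.50 (SE 0.0501) and fell by 0.40 (SE 0.0387). Of 22 cytosolic ribosomal protein genes, 7 fell and none rose, also when adjusted over the list alone, with RPL36A and RPL13A at -0.29 and -0.27. In oxidative phosphorylation 4 of 5 measured genes fell, NDE1 and CYC1 among them, and COX5B rose, also when adjusted over the list alone. In glycolysis PYK2, a minor pyruvate kinase isozyme, rose by 0.83 (SE 0.0655), and the 4 others were not past the threshold, also when adjusted over the list alone, PGK1 at 0.08 (SE 0.0404). Of 5 TCA cycle genes, 1 rose, ACO1 by 0.09 (SE 0.0313), or 0 when adjusted over the list alone, and IDH1 was at 0.11 (SE 0.0437). These 4 lists were each at an adjusted p of 0.143. Oxidative phosphorylation was called with poly-A control centring (adjusted p = 1.04e-08) and hybridization control centring (1.73e-08), and ribosomal proteins with the latter (0.027). ACO1, PGK1 and IDH1 turned negative with hybridization control centring.

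The gluconeogenesis and fatty acid oxidation lists had too few measured genes for a test. MDH2, the cytosolic malate dehydrogenase of gluconeogenesis, fell by 0.66 (SE 0.0787), and PCK1 was at 0.22 (SE 0.0857, adjusted p = 0.0606). ECI1, of fatty acid oxidation, rose by 0.40 (SE 0.0748).

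**Figure D3:**
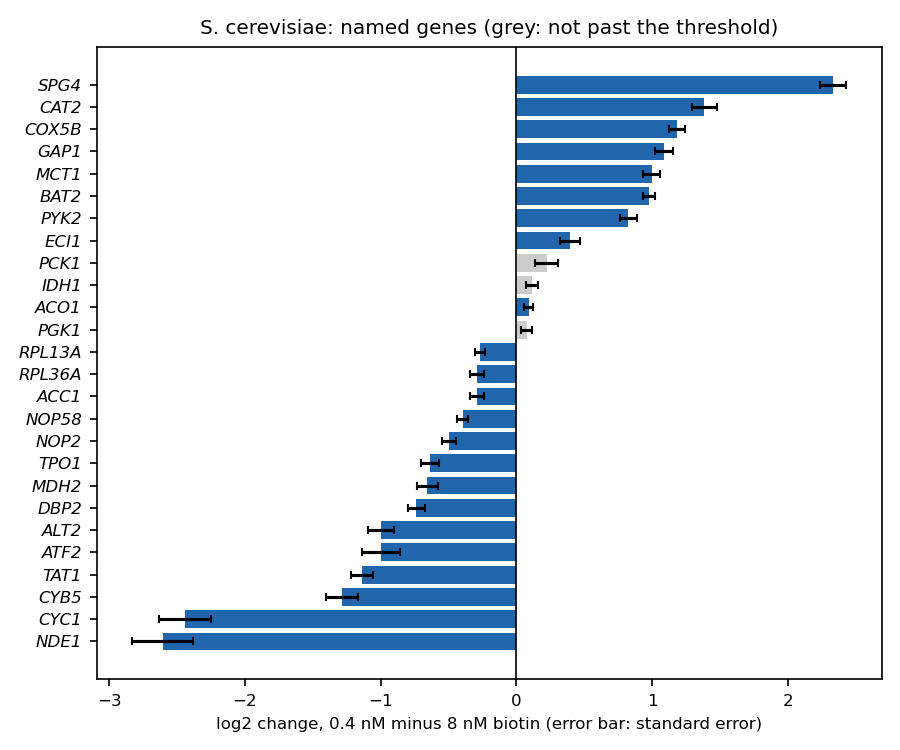
Log2 change of the 26 named yeast genes, 0.4 nM minus 8 nM biotin (n = 3 arrays each), with standard errors as error bars. Blue bars had an adjusted p under 0.05 and grey bars did not. SPG4 leads at 2.34, and NDE1 and CYC1 lie lowest at -2.61 and -2.44.

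In all, limma called 2347 of 5803 yeast probe sets, 1086 higher and 1261 lower at 0.4 nM biotin, with 80 rising and 29 falling by at least 2-fold. The groups did not overlap for 51.5% of probe sets, where chance gives 10%. The split was 1043 higher and 424 lower with poly-A control centring, and 501 were called with hybridization control centring.

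The same contrast was set side by side in the 3 organisms for the shared lists. Cytosolic ribosomal protein genes had a mean log2 shift of 0.26 in rat, -0.05 in worm and -0.09 in yeast. Rat exceeded worm by 0.314 (exact permutation p = 0.005, adjusted p = 0.0267; 0.288 without rpa-1 and rpa-2) and yeast by 0.353 (exact permutation p = 0.005, adjusted p = 0.0267). Oxidative phosphorylation genes had a mean of 0.04 in rat, 0.20 in worm and -0.94 in yeast, where 5 genes were measured. The yeast mean rested on NDE1 and CYC1, the yeast median was -0.44, and the kinds of genes on this list differ between the organisms. Rat exceeded yeast by 0.981 (exact permutation p = 0.01, adjusted p = 0.04) and worm exceeded yeast by 1.14 (exact permutation p = 0.005, adjusted p = 0.0267). With the median over list members, these excesses were 0.476 and 0.58 (exact permutation, adjusted p = 0.04 each). The ribosomal protein and oxidative phosphorylation differences were 4 of 16 comparisons, and p = 0.005 is the smallest the permutations can give. Each p is against no biotin effect in either organism, so a shift in a single organism can give it. As deposited, 0 of 16 were past the threshold, with a lowest adjusted p of 0.064. None of the 4 was past it under the 3 other scalings, with adjusted p-values from 0.0533. The oxidative phosphorylation excess of worm over yeast was 0.413 under median centring and 0.236 with poly-A control centring, and the ribosomal protein excess of rat over worm was 0.919 and 1.07. Over the other scalings, the excess of rat over yeast was 0.865 to 1.1 for oxidative phosphorylation and 0.311 to 0.541 for ribosomal proteins. With poly-A control centring, worm instead lay below yeast by 1.03 in glycolysis and 1.07 in the TCA cycle (adjusted p = 0.04 each).

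The other 12 comparisons were not past the threshold. Gluconeogenesis genes had means of 0.71 in rat and 0.84 in worm (difference -0.13, adjusted p = 0.845), but the worm mean was 0.03 under median centring and -0.04 with poly-A control centring. Fatty acid synthesis genes had means of -0.81 and -0.53 (difference -0.28, adjusted p = 0.68). Biotin enzyme genes had means of -0.16 in rat and -0.02 in worm (adjusted p = 0.4). TCA cycle genes had means of 0.13 in rat and -0.01 in worm (adjusted p = 0.16).

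**Figure D4:**
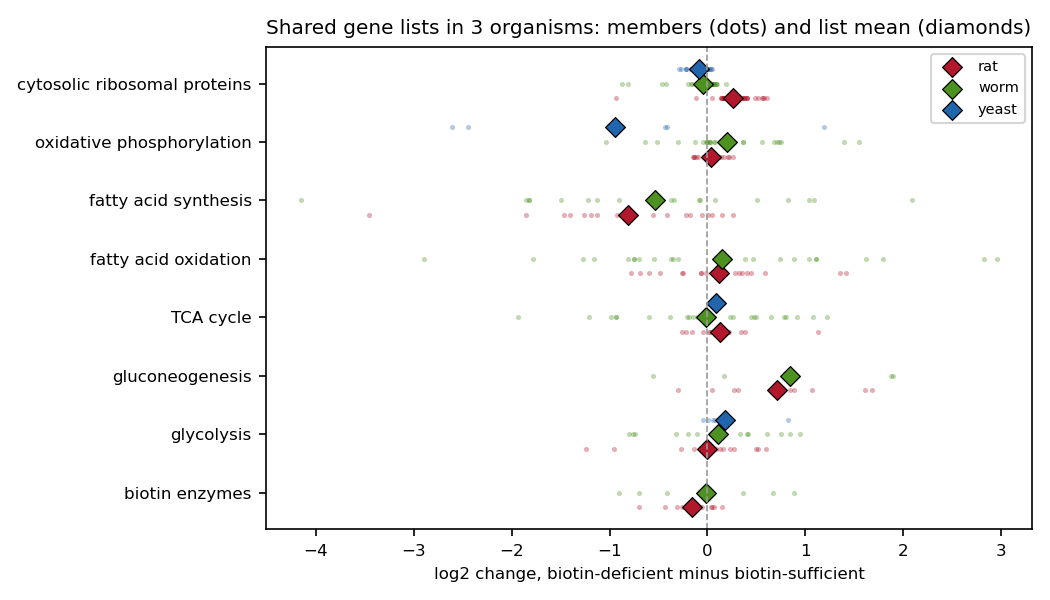
Shared gene lists in rat, worm and yeast under quantile normalization. The x axis is the log2 change, deficient minus sufficient, dots are genes (rpa-1 and rpa-2 among the worm ribosomal proteins) and diamonds are list means, and lists with fewer than 4 measured yeast genes have no yeast point. Rat ribosomal protein genes have a mean of 0.26 against -0.05 in worm and -0.09 in yeast, differences that were not past the threshold under any other scaling tried. The worm means of ribosomal proteins, glycolysis, oxidative phosphorylation, fatty acid oxidation and gluconeogenesis turned in sign under at least 1 other scaling.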

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

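The test of the poly-A controls and those of normalization and RNA quality in the worm arrays were chosen only after the results were seen.

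The shift of cytosolic ribosomal protein genes differed between rat and worm by 0.314 and between rat and yeast by 0.353. The shift of oxidative phosphorylation genes differed between rat and yeast by 0.981 and between worm and yeast by 1.14. With the median over list members, these oxidative phosphorylation differences were 0.476 and 0.58. The exact permutation behind the 4 calls takes no biotin effect in either organism as its null, so a shift in a single organism can produce them. None of the 4 differences was past the threshold as deposited, with a lowest adjusted p of 0.064, or under the 3 other scalings. Worm minus yeast fell to 0.413 under median centring and 0.236 with poly-A control centring. Over the other scalings, rat minus yeast was 0.865 to 1.1 for oxidative phosphorylation and 0.311 to 0.541 for ribosomal proteins. Rat minus worm ranged from 0.234 to 1.07. On the yeast array, 2 of the 32 probe sets named for S. pombe above the floor changed, rpl13 at -0.97 (adjusted p = 0.00714) and ubc7 at 0.48 (adjusted p = 0.0251), the former at a mean signal of 17.4, against a floor of 10.5.

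The poly-A control transcripts added to the worm samples had a signal 0.862 higher on the log2 scale in the deficient arrays, in 12 of 12 probe sets and with every deficient array above every sufficient one. The same shift was 0.0297 in rat and -0.0747 in yeast. The hybridization controls of the worm arrays were 0.172 higher in the deficient arrays. This held in 9 of 9 probe sets, again with every deficient array above every sufficient one. The poly-A shift exceeded theirs by 0.69. The amount of poly-A control added per worm sample is not known, so worm values with poly-A control centring assume equal amounts.

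Beside that shift, 9975 worm probe sets changed, and normalization between arrays cannot be the whole cause, because the highest rank correlation between a deficient and a sufficient worm array was 0.802, against 0.973 to 0.991 within groups, and ranks do not depend on scaling. A smaller share of polyadenylated RNA, which would scale all transcripts alike, is argued against as the whole cause by the same ranks. With poly-A control centring, 9127 probe sets were called, 2240 higher and 6887 lower. That total does not argue against a smaller share, because such centring would show it as lower transcripts rather than remove it. A smaller share alone would not, however, make 2240 higher. Lower RNA quality in 1 group is argued against by 3' to 5' signal ratios: the largest difference between groups was -0.301 (log2) over the 6 control transcripts above the floor, although 4 of the 6 did not overlap. An earlier point of germline development may contribute, but the marker genes cannot decide it. Under quantile normalization, 14 of 14 further oogenesis genes fell (mean -1.26, SE 0.0578). The oocyte and eggshell genes had already fallen on the same arrays, so this adds little. Of 13 further sperm genes 8 fell too (mean -0.672, SE 0.0874), and such a mean moves with the scaling. It was just short of a bound for excluding an earlier point. The bound was set before this test, on lists chosen after seeing the data. It could not decide the question, because larvae at an earlier point can be low in sperm transcripts too. Among these 8, spe-11, spe-41 and ssq-2 had higher deposited signals in the deficient arrays, and the rest had lower ones. Of 23 major sperm protein genes 12 rose, with a shift relative to other genes of 0.339, or 0.04 under the other scalings. On the same arrays the muscle, neuron, intestine, collagen and molting lists rose relative to other genes. Whether these rises and the fall of oocyte genes are separate changes was not tested. The change in biotin itself remains an untested explanation.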

How the results depend on the processing

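Centring on control transcripts, centring on the median for the organism differences and leaving rpa-1 and rpa-2 out were chosen after seeing the data, every other alternative before. The cause of the changes below was not tested, except that leaving out arrays leaves fewer samples and a fold threshold is an added condition. Counts of called probe sets that moved by more than 1.5 times, and the ranges over left-out arrays, were as follows. In rat, 1717 were called without the intensity trend, 1882 with poly-A control centring and 469 at 2-fold, and leaving out 1 array gave 1884 to 2377, lowest without sufficient replicate 3. In worm, 4800 were called at 2-fold, and leaving out 1 array gave 8317 to 10228, where the lone sufficient array is assumed to vary like the other group. In yeast, 1467 were called with poly-A control centring, 501 with hybridization control centring and 109 at 2-fold, and leaving out 1 array gave 1892 to 2269. Called lists fell from 9, 11 and 1 to 0 in rat, worm and yeast with an estimated correlation, and fry, which tests whether a list moves 1 way without comparing it with other genes, gave 21 in worm and 7 in yeast. Leaving out 1 array gave 7 to 10 called lists in rat and 10 to 11 in worm. Organism differences past the threshold went from 4 to 0 as deposited, under median centring and with hybridization control centring, and to 2 others with poly-A control centring.

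Same-numbered samples had deviations correlated at -0.0616, 0.0264 and 0.0373 in rat, 0.042 and -0.0134 in worm and 0.198, 0.198 and 0.0456 in yeast. The numbers were not taken to pair the samples, as not every pair was over 0.1, but each yeast array correlated best with its own number, a hint that they may. With a replicate block the counts were 2367 probe sets in rat, 9646 in worm and 2481 in yeast, and 9, 11 and 1 lists.

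Directions turned for some named genes. In rat under median centring, Slc5a6 was at -0.042, Pccb at -0.089 and Acaca at -0.076. With poly-A control centring Pccb was at -0.012 and Acacb at 0.021. Acacb was at 0.050 as deposited and 0.052 with hybridization control centring. Other probe sets gave -0.13 for Acaca and 0.56 for Apob. Leaving out 1 array gave -0.0078 to 0.15 for Slc5a6, -0.050 to 0.085 for Pccb, -0.089 to 0.20 for Acaca and -0.22 to 0.24 for Acacb. In worm under median centring, pcca-1 was at -0.063, pccb-1 at -0.18, pyc-1 at -0.67, msp-142 at -0.18, msp-74 at -0.17 and msp-3 at -0.35. With poly-A control centring pcca-1 was at -0.13, pccb-1 at -0.25, pyc-1 at -0.74, gpd-3 at -0.040, msp-142 at -0.25, msp-74 at -0.24 and msp-3 at -0.42. Another pccb-1 probe set was at -0.28, pyc-1 was at -0.050 with hybridization control centring and bpl-1 at 0.048 as deposited. In yeast with hybridization control centring, PGK1 was at -0.059, ACO1 at -0.049 and IDH1 at -0.033. Across all alternatives, 25 of 56 named rat genes, 45 of 63 worm genes and 8 of 26 yeast genes kept both direction and side of the threshold, the 2-fold condition included. Dim signals are limited by the floor and the offset of 16.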

Other observations

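The tests of neutrophils, of hepatocyte share and of growth hormone signal were chosen after the result was seen, and so were the genes of the sex-pattern lists, several of which had been seen to change. The genes in this paragraph and the next were chosen after their values were seen, from lists fixed before the data were examined that were not called. In rat liver, insulin signalling genes went both ways, 3 of 12 rising and 2 falling: Igfbp1, an insulin-suppressed binding protein, rose by 3.08 and Irs2 by 1.67, while Pik3r1 fell by 1.52 (list mean 0.28, median -0.0004, camera adjusted p = 0.529). Antioxidant genes also split, 4 of 15 rising and 7 falling, with the glutathione transferase gene Gsta3 at 2.14 and the glutathione reductase gene Gsr at -1.07 (list mean 0.06, median -0.11, adjusted p = 0.513). Cell cycle genes were mostly not past the threshold, but Ccnd1, cyclin D1, fell by 2.83. In the urea cycle 2 of 7 rose, Asl by 1.07 and Ass1 by 0.29, and 2 fell, Slc25a15 at -0.36 and Otc at -0.20 (adjusted p = 0.529).

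In worm, 4 of 5 genes of the propionate shunt fell and 1 rose: acdh-1 fell by 2.89, hphd-1 fell by 1.62 and alh-8 rose by 1.55 (adjusted p = 0.142). Vitellogenin genes fell in 4 of 5 cases, vit-1 by the most at -3.04 (adjusted p = 0.154). In yeast, 5 of 7 ergosterol genes fell and 1 rose, with HMG1 at -0.69 and HMG2 at 0.19 (adjusted p = 0.142), and CAR2, of arginine use, rose by 0.95. Of 5 iron regulon genes 1 rose and 1 fell, SIT1 at 0.66 and HMX1 at -0.78 (adjusted p = 0.391). When adjusted over the list alone, 6 antioxidant genes rose and 7 fell, 1 ergosterol gene rose and 6 fell, and the counts of the insulin, propionate, vitellogenin and iron lists were the same.

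The rat acute phase and macrophage rises may involve neutrophils: Mmp8, S100a8 and S100a9 rose, with a median of 2.28 (mean 2.06, SE of the mean 0.336), but they were the only 3 of 9 markers past the filter on mean signal, and the median over all 9 was 0.737. Of the 6 below it, Itgam went from 15.9 to 79 and Csf3r from 8.59 to 27.3, but Camp and Cxcr2 stayed at 8.85 and 22.5 in the deficient livers, and macrophages also express S100a8 and S100a9, so neutrophils and a change in resident cells cannot be told apart. A lower share of hepatocytes is argued against as the whole cause of the macrophage rise. The macrophage list moved 0.567 (SE over genes 0.202) above the stellate cell and lymphocyte lists, and 0.442 (SE 0.153) with the endothelial list added to these. These errors treat genes of the same livers as independent, and the acute phase genes were not part of the comparison. A lower share of hepatocytes may still contribute, because the endothelial mean was 0.39 and the hepatocyte mean -0.14, although 3 of 7 stellate markers fell. The hepatocyte mean is weak evidence: it was -0.05 as deposited, and that list was called only under quantile normalization. The diet itself remains an untested explanation.

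Genes that are higher in female rat liver rose in 4 of 6 measured cases, with Cux2 at 3.43, Trim24 at 3.39, Cyp2c12 at 2.18 and Prlr at 1.75, and Cyp2c7 and A1bg not past the threshold. All 8 measured male-predominant genes fell, with Obp3 at -4.02 and Sult1e1 at -0.92; the growth hormone list also holds 4 of the 8, all cytochrome P450 genes. Female rats among those labelled deficient are argued against, because Y-linked Eif2s3y and Uty in the lowest deficient array lay no further than -0.75 from the sufficient mean, and Xist stayed below the filter. A changed growth hormone signal is a candidate explanation: 6 growth hormone responsive genes of both sexes had a mean of -0.447 (SE 0.174), although Igfbp3, Socs2 and Cish were not past the threshold. It remains a hypothesis, found and tested on the same livers.

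There are 10 splits of 6 arrays into 3 and 3, too few for a share under 0.05. Every split but the real one mixes the biotin levels within both groups, so a difference between the levels widens its spread. Its count therefore does not estimate the calls made by chance. In rat, the real split called 2895 probe sets and the highest other 0, so 1 of 10 was as large, and for lists the numbers were 9 and 5, again 1 of 10. In yeast, the real split called 2347 probe sets and the highest other 0, 1 of 10. The real yeast split called 1 list and the highest other 2, with 8 of 10 as large.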
